A study of Saccharomyces cerevisiae BY4741 with 15 samples.

How the data were processed

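The RNA-seq of Saccharomyces cerevisiae strain BY4741 covered 4 groups with 2 libraries each: exponential growth in glucose medium (YPD), and 5, 15 or 60 min after a switch to galactose medium (YPG). Per the labels' protocols, cells were collected by filtration, flash-frozen and ground, total RNA was extracted with phenol and chloroform, ribosomal RNA was depleted with a RiboMinus kit, and libraries were built with the Ion Total RNA-seq kit v2, a kit that keeps the strand of the RNA. Another 7 samples of the series, 4 of MNase-seq and 3 of NET-seq, were not analysed here.

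Each RNA library was deposited as 1 list of aligned reads with chromosome, start, end and strand. The list has no header and no score or coverage value, so every count and CPM below was made here. Per the submitters' processing notes, Bowtie and SAMtools were used and the build was sacCer3. Their versions, their settings and the treatment of reads that match several places are not given in the sources used here. Reads of near-identical gene copies (HXT6 and HXT7, TDH1 to TDH3, ENO1 and ENO2, PHO11 and PHO12, SSA1 and SSA2, TEF1 and TEF2, paired ribosomal protein and histone genes) can therefore be lost or swapped between copies, and the values of such genes are uncertain.

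Genes came from a RefSeq table of the R64 assembly, which is the assembly that sacCer3 names. The table gives spans without exons, and the strand was read from the W or C of the locus tag. Of its 6477 genes, 10 rDNA precursor and spacer entries and 1 entry without a strand were left out, leaving 6466, of which 6002 were nuclear protein-coding genes. A read was assigned when it overlapped exactly 1 gene on the same strand, and the 46 mitochondrial genes were counted on either strand. Between 90.5% and 94.8% of each library's reads were assigned. Reads of overlapping genes are lost by this rule: GAL1 lies inside the annotated antisense RNA YNCB0008W and had no assigned read, so its values come from a setting, chosen after seeing the data, in which the 7 antisense RNA entries were left out.

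The test was to be a count model, with a stated fallback if the deposited unit ruled one out. For aligned reads the plan foresaw counting per gene here. The lists have no column of counts, and the fallback was taken as the main test: limma-trend on log2(CPM + 1), with the same samples and design. A count model of the reads counted here would also have been possible and was not run, so the main test departs from the plan. Scaling used TMM factors (30% of M and 5% of A values trimmed), computed here. A gene was tested with at least 10 reads, scaled to library size, in at least 2 libraries and at least 15 reads in all, which left 5776 genes. All 8 libraries entered 1 fit of group means (residual degrees of freedom 4, prior degrees of freedom 5.34), so the groups share 1 estimate of the spread, and the median SE of a log2 fold change was 0.25. The 5 contrasts were each time against glucose, 15 min against 5 min and 60 min against 15 min. Every adjusted p of a gene is from limma's moderated test with Benjamini-Hochberg adjustment over the tested genes, and a gene was called below 0.05. A fold change on the log2(CPM + 1) scale understates the change of genes with few reads. An exact permutation of 2 libraries against 2 cannot go below 0.333, so no such test was made. The labels do not say that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

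In all, 33 gene lists were fixed before the data were examined. So were the design, apart from the choice of main test above, the rule for named genes and all alternatives except those said to be chosen later. They cover the galactose regulon, hexose transporters, glucose signalling, gluconeogenesis and the glyoxylate cycle, ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, translation factors, the general stress response, trehalose and glycogen, Hsf1 chaperones, oxidative stress defence, glycolysis and fermentation, the TCA cycle, the respiratory chain with ATP synthase, the mitochondrial ribosome, fatty acid oxidation and peroxisomes, the proteasome and autophagy. The others are amino acid biosynthesis (Gcn4 targets), sulfur and methionine, purine synthesis and one-carbon metabolism, ergosterol synthesis, the phosphate and iron regulons, genes of G1 to S, G2 to M and M to G1 phase, histones, markers of a cells, of alpha cells and of meiosis, and the genes deleted in the strain. Each list with at least 3 tested members was tested with limma's camera at a preset correlation of 0.01, which compares the list with the other genes, with Benjamini-Hochberg adjustment over the lists of a contrast. None of the camera calls held with an estimated correlation in any of the 5 contrasts. That version rests on 4 residual degrees of freedom and has little power here. Every list is therefore described by its members' own calls, and the p with an estimated correlation is printed beside each. Not tested for lack of reads were HXT9, HXT13 to HXT17, MF(ALPHA)1, SPO11, SPO13 and SPS2.

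The rule for named genes took, for each time against glucose, the 10 largest rises and the 10 largest falls among called protein-coding genes with a standard symbol, an average log2 CPM of at least 4, and both libraries of one group above both of the other. Between times it took 5 each way. It also took all members of the galactose, hexose transporter and strain deletion lists, and for every other list up to 4 called members with the largest change or, with none called, the 2 with the smallest p. For antisense reads it took the 5 largest changes each way among called genes with an average of at least 20 antisense reads. Some results of genes that the rule took are not reported here.

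Antisense reads were counted on the opposite strand of protein-coding genes, in the part of each gene more than 300 bp from any annotated gene on that strand, with at least 200 bp searched (5664 genes, or 5088 with a distance of 600 bp). They were scaled with the sense factors and library sizes and tested in the same design. Reads under 30 bp made up 3.54% to 8.81% of the libraries. Because their placement differed between groups, all counts were repeated with reads of at least 30 bp, a setting chosen after seeing the data, as was a fit without the 15 min libraries. Places of short reads were compared in bins of 10 bp, present with at least 20 reads in both libraries of a group and missing with at most 2.

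Alternatives covered other scaling (library totals, RLE size factors, upper quartile, TMM without the ribosome lists), other filters, a pseudocount of 0.25, limma voom, the replicate number as a block, only the 4 libraries compared, stricter thresholds, counting by the 5-prime end, on either strand or with position duplicates collapsed, thinning of every library to 2154304 assigned reads (seed 1), and leaving out each library in turn. For lists they also covered fry, and for antisense reads the 600 bp distance and antisense factors. Intron reads were not analysed here, since the gene table has no exons.

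The fit was tested on simulated data: reads were drawn for 5776 genes from the real means and library sizes, with 200 genes changed in the 60 min group (seed 7). Of the 5732 genes then tested, the 60 min against glucose contrast recovered 10.4% of the changes of 1.5 times, 30% of 2 times, 92% of 4 times and 98% of 8 times, with 4 of 5534 unchanged genes called. The real contrasts of 15 and 60 min with glucose called 50.6% and 48.5% of genes. So many changed genes were not simulated, and these rates do not give the recovery or false calls of those contrasts. For contrasts that share the glucose libraries, shared calls and the correlation of fold changes were also computed in 20 simulations with no effect (seed 11). Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.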

Results

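The series asked how RNA polymerase II occupancy, transcript levels and nucleosome positions change when yeast are moved from glucose to galactose, and the RNA-seq analysed here bears on the transcript levels. BY4741 is a haploid laboratory strain of mating type a, derived from S288C. It was sampled in exponential growth on glucose (OD600 of 0.65) and 5, 15 and 60 min after the switch, with 2 libraries per group. Samples labelled as resuspended in YPD are in the NET-seq alone. In the RNA-seq, effects of the transfer itself therefore cannot be told apart from those of the change of sugar. The libraries held 4374466 and 3573519 aligned reads in glucose, 8393099 and 3753562 at 5 min, 3685285 and 3547179 at 15 min, and 3863617 and 2373632 at 60 min. Across genes, log2 CPM of libraries of the same group correlated with Pearson r from 0.955 (5 min) to 0.980 (60 min), and libraries of different groups with 0.718 to 0.954. These describe agreement only, since genes are not independent replicates. Same-group libraries differed by more than counting noise (chi-square per degree of freedom 8.68 to 50.3), which separate library preparation alone can give, and each library was counted as 1 replicate. Among the 4 groups, 3295 of the 5776 tested genes (57.0%) changed at some time by limma's F-test.

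The genes deleted in the strain were examined first as a check of the strain label. BY4741 lacks LEU2, MET17 and URA3, which serve the synthesis of leucine, methionine and uracil, and carries a partial deletion of HIS3, a gene of histidine synthesis. LEU2 (YCL018W, chromosome III, 91324 to 92418, plus strand), MET17 (YLR303W, chromosome XII, 732542 to 733876, plus strand) and URA3 (YEL021W, chromosome V, 116167 to 116970, plus strand) had 0 reads of at least 30 bp in all 8 libraries, and 1 to 109 shorter reads. These genes still passed the filter for testing, so low counts of other genes can hold misplaced short reads too. HIS3 (YOR202W, chromosome XV, 721946 to 722608, plus strand) had reads, in most libraries mainly near its end, from position 722387. Its level was 429 ± 145 CPM in glucose, 432 ± 142 CPM at 5 min, 10.0 ± 3.78 CPM at 15 min and 213 ± 12.8 CPM at 60 min. By the rule for named genes this was the largest value below glucose at 15 min (log2 fold change -5.29 ± 0.32, SE, adjusted p = 2.87e-06). Reads near its end were 1056 of 1159 and 1496 of 1552 in glucose, 3921 of 4059 and 980 of 1054 at 5 min, 20 of 46 and 13 of 27 at 15 min, and 762 of 807 and 489 of 509 at 60 min. A different culture or strain stock at 15 min was not excluded, so the HIS3 values that involve 15 min are not read as a change over time. The same limit holds for every other gene compared with 15 min below, where rises and falls are differences between these libraries. Its lower value at 60 min (-0.97 ± 0.32) was lost without glucose replicate 2 or either 60 min library, adjusted p = 0.106 to 0.296, and with scaling by library totals at 0.108.

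Within 5 min of the switch, some genes of protein folding and of carbohydrate storage rose while few genes were called lower. The number called lower depended on single libraries, as given below. At 5 min replicate 2 correlated with glucose replicate 1 (Pearson r = 0.954) about as closely as with 5 min replicate 1 (0.955). HSP30, a stress-induced protein of the plasma membrane (YCR021C, chromosome III, 156109 to 157107, minus strand, coordinates of sacCer3 here and below), went from 3.97 ± 0.762 to 288 ± 47.1 CPM (mean ± SD, n = 2 in each group throughout), a log2 fold change of 5.86 ± 0.35 (SE), or 58.1 times higher. BTN2, which gathers misfolded proteins, rose from 17.0 ± 1.79 to 396 ± 123 CPM, and GSY1, a glycogen synthase, from 19.7 ± 5.58 to 283 ± 42.7 CPM. PGM2, the phosphoglucomutase that serves both galactose use and glycogen synthesis (YMR105C, chromosome XIII, 475897 to 477606, minus strand), rose from 30.6 ± 7.09 to 221 ± 48.5 CPM. The galactose genes GAL10, GAL7 and GAL2 were at 2.92 ± 2.09, 2.58 ± 0.985 and 2.57 ± 0.0759 CPM, against 2.81 ± 0.390, 1.93 ± 1.14 and 3.82 ± 3.81 CPM in glucose, and did not pass the test. YHP1, a repressor of early G1 genes, fell from 66.6 ± 24.9 to 16.1 ± 3.48 CPM (-1.95 ± 0.30, adjusted p = 0.00371).

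The other largest rises at 5 min were ROQ1, which retargets the ubiquitin ligase Ubr1 (log2 fold change 5.08 ± 0.25), TMA10, a ribosome-associated protein (4.92 ± 0.27), and HSP42, a small heat shock protein (4.07 ± 0.32). CMK2, a calmodulin-dependent kinase, rose by 3.96 ± 0.30, followed by MGA1 (3.94 ± 0.41), MPC3, a subunit of the mitochondrial pyruvate carrier (3.88 ± 0.27), BDH2 (3.87 ± 0.26) and FMP48 (3.87 ± 0.28). Their adjusted p ran from 2.23e-05 (ROQ1) to 0.000365 (MGA1). The rule itself required both libraries at 5 min to lie above both in glucose. The falls were smaller. PCL1, a cyclin of the Pho85 kinase, fell by 1.61 (adjusted p = 0.00472). FAR1, which arrests the cycle in response to pheromone, fell from 324 ± 24.1 to 131 ± 1.18 CPM (adjusted p = 0.00179). The other falls of the rule depended on single libraries. PHM6 (-1.92) was lost without either glucose library or 5 min replicate 1, adjusted p = 0.0827 to 0.148. SFG1 (-1.21) was lost without either glucose library, adjusted p = 0.0525 to 0.101. AIR1 (-1.19) was lost without either glucose library or 5 min replicate 1, adjusted p = 0.0543 to 0.133. HO (-1.14) was lost without either glucose library, adjusted p = 0.0629 to 0.141. HCM1 (-1.13) was lost without either glucose library, 5 min replicate 1, either 15 min library or either 60 min library, adjusted p = 0.0555 to 0.147. RPS28B (-1.10) was lost without either glucose library or either 60 min library, adjusted p = 0.0572 to 0.253. IBD2 (-1.07) was lost without either glucose library, 5 min replicate 2, either 15 min library or either 60 min library, adjusted p = 0.0610 to 0.245.

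By group at 5 min, 22 of the 46 measured genes of the general stress response rose, 0 fell and 24 did not pass the test (28 rose adjusted over the list alone, median log2 fold change 1.32, camera adjusted p = 3.08e-19, and adjusted p = 0.215 with an estimated correlation). Examples are STF2, a stabiliser of the ATP synthase inhibitor (3.56 ± 0.27), RGI1, a protein of respiratory growth (3.13 ± 0.34), and the cell wall protein SPI1 (3.23 ± 0.41). Trehalose and glycogen genes moved the same way, with 10 of 18 higher and 0 lower (14 higher adjusted over the list alone, camera adjusted p = 2.48e-12, and adjusted p = 0.215 with an estimated correlation). The branching enzyme GLC3 rose by 3.62 ± 0.19 and glycogenin GLG1 by 2.35 ± 0.18. Among chaperone genes under Hsf1, 12 of 26 rose and 0 fell (15 rose adjusted over the list alone, camera adjusted p = 4.87e-11, and adjusted p = 0.215 with an estimated correlation). The Hsp40 protein APJ1 rose by 3.38 ± 0.21 and the mitochondrial disaggregase HSP78 by 2.85 ± 0.25.

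Some genes of sugar uptake and phosphorylation were also higher at 5 min. Of the 12 measured hexose transporter and sensor genes, 4 rose and 0 fell (5 rose adjusted over the list alone, camera adjusted p = 0.00155, and adjusted p = 0.215 with an estimated correlation). HXT4 went from 28.3 ± 8.51 to 159.8 ± 3.44 CPM and HXT2 from 183 ± 21.9 to 712 ± 105 CPM. HXT6 and HXT7, near-identical copies that share reads, rose by 2.17 ± 0.31 and 2.02 ± 0.26. HXT6 did not pass in a fit of only the 4 libraries compared (adjusted p = 0.0909). HXT1 and HXT3, carriers used at high glucose, had values of 0.22 ± 0.22 and 0.69 ± 0.28 and did not pass. Of 10 galactose regulon genes 3 rose and 0 fell, as they did adjusted over the list alone (camera adjusted p = 0.00388, and adjusted p = 0.215 with an estimated correlation). Beside PGM2 they were MTH1, a repressor of hexose transporter genes (1.63 ± 0.31, lost without glucose replicate 1, adjusted p = 0.0838), and GCY1, a glycerol dehydrogenase (1.35 ± 0.27, lost without glucose replicate 2 or 5 min replicate 1, adjusted p = 0.0951 to 0.175). Glycolysis had 5 of 21 members higher and 0 lower (5 higher adjusted over the list alone, camera adjusted p = 0.00388, and adjusted p = 0.428 with an estimated correlation). They include hexokinase HXK1 (2.41 ± 0.30), glucokinase GLK1 (2.21 ± 0.22) and, with reads shared among close copies, TDH1 (3.03 ± 0.22) and ENO1 (2.06 ± 0.25).

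Ribosome and cell cycle lists had negative medians at 5 min with few members called. Ribosomal protein genes had a median of -0.38, with 0 higher and 2 of 138 lower (0 adjusted over the list alone, camera adjusted p = 1.86e-11, and adjusted p = 0.531 with an estimated correlation). Ribosome biogenesis genes had a median of -0.30 with 0 of 138 called either way, also adjusted over the list alone (camera adjusted p = 6.31e-08, and adjusted p = 0.641 with an estimated correlation). By fry, which asks whether a list's own genes move 1 way, these lists did not pass (adjusted p = 0.293 and 0.460). The 2 ribosomal protein genes were RPS28B and RPL14B (-0.95, lost without either glucose library, 5 min replicate 1 or either 60 min library, adjusted p = 0.0788 to 0.223). In G1 to S phase 2 of 17 genes fell (5 adjusted over the list alone, camera adjusted p = 2.49e-05, and adjusted p = 0.215 with an estimated correlation). These were PCL1 and the cyclin CLB5 (-0.93), which was lost without either glucose library, either 15 min library or 60 min replicate 1, adjusted p up to 0.210. In G2 to M phase 2 of 12 fell (7 adjusted over the list alone, camera adjusted p = 7.28e-07, and adjusted p = 0.215 with an estimated correlation). The deacetylase HST3 went from 86.9 ± 24.5 to 42.1 ± 4.07 CPM, lost without glucose replicate 1, 5 min replicate 1, either 15 min library or either 60 min library, adjusted p = 0.0513 to 0.228. The polo kinase CDC5 (-0.88) was lost without either glucose library, adjusted p = 0.112 to 0.147.

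Other lists at 5 min had 5 or fewer called members. Fatty acid oxidation rose in 5 of 20 (8 adjusted over the list alone, camera adjusted p = 0.00363, and adjusted p = 0.428 with an estimated correlation). Autophagy genes rose in 4 of 28 (7 adjusted over the list alone, camera adjusted p = 0.00405, and adjusted p = 0.428 with an estimated correlation), a list call lost without glucose replicate 1, adjusted p = 0.0540. The mitochondrial ribosome rose in 2 of 67 (1 adjusted over the list alone, camera adjusted p = 0.00365, and adjusted p = 0.531 with an estimated correlation), 1 of them MRP8 (1.52 ± 0.22), whose place in the mitochondrial ribosome is uncertain, and did not pass with fry (adjusted p = 0.0930). Glucose signalling rose in 2 of 23, also adjusted over the list alone (camera adjusted p = 0.00591, and adjusted p = 0.215 with an estimated correlation), lost without 5 min replicate 2, adjusted p = 0.0668. Its members called were GPA2, the G protein alpha subunit of glucose sensing (1.91 ± 0.17), and the protein kinase A subunit TPK2 (from 33.4 ± 4.55 to 98.4 ± 31.0 CPM), lost without glucose replicate 2, adjusted p = 0.0638. Polymerase I and III subunits fell in 2 of 21, also adjusted over the list alone (camera adjusted p = 0.000299, and adjusted p = 0.428 with an estimated correlation, and 0.156 with fry). Markers of a cells had 0 of 7 called (median -0.51, camera adjusted p = 0.00733, and adjusted p = 0.215 with an estimated correlation), lost without glucose replicate 1, adjusted p = 0.0849. The proteasome had 0 of 33 called (median 0.30, camera adjusted p = 0.0170, and adjusted p = 0.706 with an estimated correlation), lost without glucose replicate 2 or 5 min replicate 1, adjusted p = 0.133 to 0.848. Purine synthesis fell in 1 of 17, also adjusted over the list alone (camera adjusted p = 0.0253, and adjusted p = 0.706 with an estimated correlation), lost without glucose replicate 1 or 5 min replicate 1, adjusted p = 0.0540 to 0.183.

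In total 322 genes were higher and 29 lower at 5 min than in glucose, and 5425 of 5776 did not pass. Of those called, 266 and 18 changed at least 2 times. The counts were 366 and 34 with reads of at least 30 bp, and without the 15 min libraries 262 and 19. Single libraries moved both counts. The higher genes numbered 175 and 177 without glucose replicates 1 and 2 and 487 without 5 min replicate 2. The lower genes numbered 9 and 4 without those glucose libraries, 13 and 453 without 5 min replicates 1 and 2. They came to 15 without either 15 min library and 12 without either 60 min library. Of the 64 named calls at 5 min, 30 were lost without at least 1 library.

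At 15 min transcripts of ribosomal proteins and ribosome biogenesis were lower, and those of storage, stress and respiratory genes higher, across most of their members. HSP12, a membrane-stabilising stress protein (YFL014W, chromosome VI, 107256 to 107585, plus strand), went from 13.4 ± 0.986 to 2516 ± 1503 CPM and PGM2 from 30.6 ± 7.09 to 2129 ± 279 CPM, 67.9 times higher. HXK1, a hexokinase held low on glucose, went from 75.4 ± 22.3 to 4244 ± 1202 CPM. SPB1, a methyltransferase of ribosome assembly (YCL054W, chromosome III, 31449 to 33974, plus strand), fell from 335 ± 28.3 to 13.7 ± 2.85 CPM. RNR1, the large subunit of ribonucleotide reductase, fell by 3.78. Both 15 min libraries also held 186 places of reads under 30 bp that no other group had (10003 and 15219 reads), a measured feature of this group's libraries that accompanies each comparison with 15 min below.

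The largest rises at 15 min were TMA10 (log2 fold change 8.19 ± 0.27), RGI1 (7.47 ± 0.34), HSP12 (7.31 ± 0.38), DDR2 (6.76 ± 0.41), and MPC3 (6.67 ± 0.27). Next came EGO4 (6.66 ± 0.30), HSP30 (6.51 ± 0.35), RGI2 (6.50 ± 0.44), the lactate carrier JEN1 (6.49 ± 0.40) and GLC3 (6.40 ± 0.19). With HIS3 set aside, the largest falls were SPB1 (-4.52 ± 0.20), CGR1, of ribosomal RNA processing (-4.46 ± 0.29), the helicase DBP7 (-4.39 ± 0.19), and HO, the endonuclease of mating-type switching (-4.32 ± 0.22). SFG1 (-4.26 ± 0.23), MAK16 (-3.94 ± 0.33), the nucleolar protein NSR1 (-3.87 ± 0.33), RSA4 (-3.85 ± 0.35) and RNR1 (-3.78 ± 0.29) followed. Adjusted p for these genes ranged from 2.47e-07 (TMA10) to 2.78e-05 (RSA4). Both libraries at 15 min lay on the same side of both in glucose, as the rule required.

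Ribosome biogenesis was lower in 133 of 138 members and higher in 0 (136 lower adjusted over the list alone, median -2.32, camera adjusted p = 1.43e-32, and adjusted p = 0.236 with an estimated correlation). Ribosomal protein genes were lower in 126 of 138 and higher in 0 (130 lower adjusted over the list alone, median -1.48, camera adjusted p = 1.70e-22, and adjusted p = 0.238 with an estimated correlation). RPS28B (-3.35 ± 0.24) and RPS9A (-2.59 ± 0.20) are examples, and their reads can be shared with their copies. Subunits of RNA polymerases I and III fell in 20 of 21 (20 adjusted over the list alone, camera adjusted p = 1.22e-09, and adjusted p = 0.230 with an estimated correlation). RPC19, shared by both enzymes, was at -3.54 ± 0.25. Translation factors fell in 29 of 34 and rose in 1, with the same counts adjusted over the list alone (camera adjusted p = 1.48e-08, and adjusted p = 0.236 with an estimated correlation). The elongation factor YEF3 went from 15164 ± 827 to 3447 ± 1441 CPM. Purine synthesis fell in 15 of 17 (16 adjusted over the list alone, camera adjusted p = 2.84e-05, and adjusted p = 0.284 with an estimated correlation). ADE6 was at -2.11 ± 0.28. Amino acid synthesis fell in 27 of 39 and rose in 2, as it did adjusted over the list alone (camera adjusted p = 5.41e-05, and adjusted p = 0.348 with an estimated correlation). Asparagine synthetase ASN1 was at -2.14 ± 0.26. Ergosterol synthesis fell in 18 of 23 and rose in 2, also adjusted over the list alone (camera adjusted p = 2.84e-05, and adjusted p = 0.236 with an estimated correlation). ERG11, the target of azole drugs, was at -2.59 ± 0.22.

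On the rising side, 44 of 46 general stress genes were higher and 0 lower, also adjusted over the list alone (median 4.10, camera adjusted p = 1.70e-22, and adjusted p = 0.230 with an estimated correlation). So were 17 of 18 trehalose and glycogen genes, also adjusted over the list alone (camera adjusted p = 2.34e-12, and adjusted p = 0.230 with an estimated correlation), and glycogen phosphorylase GPH1 rose from 45.3 ± 11.1 to 2803 ± 372 CPM. The respiratory chain and ATP synthase were higher in 32 of 33 and lower in 0 (33 higher adjusted over the list alone, camera adjusted p = 1.04e-10, and adjusted p = 0.236 with an estimated correlation). The NADH dehydrogenase NDI1 rose by 4.01 ± 0.29 and HAP4, the activator of respiratory genes, by 3.30 ± 0.27. Fatty acid oxidation and peroxisome genes were higher in 17 of 20 (18 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.56e-08, and adjusted p = 0.230 with an estimated correlation). The thiolase POT1 was at 4.88 ± 0.34 and the activator ADR1 at 3.75 ± 0.26. Gluconeogenesis and the glyoxylate cycle were higher in 15 of 18 (16 adjusted over the list alone, camera adjusted p = 1.62e-06, and adjusted p = 0.236 with an estimated correlation). Invertase SUC2 was at 3.04 ± 0.16 and the activator CAT8 at 2.94 ± 0.32. The TCA cycle was higher in 11 of 16, also adjusted over the list alone (camera adjusted p = 0.000265, and adjusted p = 0.238 with an estimated correlation). Citrate synthase CIT1 was at 3.16 ± 0.26. Autophagy genes were higher in 21 of 28, also adjusted over the list alone (camera adjusted p = 5.56e-07, and adjusted p = 0.230 with an estimated correlation). ATG8 was at 3.35 ± 0.31.

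Most genes of G1 to S and G2 to M phase were down at 15 min. In G1 to S phase 13 of 17 fell, also adjusted over the list alone (camera adjusted p = 2.84e-05, and adjusted p = 0.230 with an estimated correlation), PCL1 by 3.04. In G2 to M phase 9 of 12 fell, also adjusted over the list alone (camera adjusted p = 0.00199, and adjusted p = 0.236 with an estimated correlation), the cyclin CLB2 by 2.34. M to G1 phase had 2 of 10 higher and 1 lower (mean -0.07, median -0.01, or 0.32 under another scaling, test direction higher, camera adjusted p = 0.958). The phosphate regulon fell in 10 of 14 and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0204, and adjusted p = 0.526 with an estimated correlation), a list call lost without 15 min replicate 2, adjusted p = 0.0637. Its transporter PHO84 fell by 2.99. Sulfur genes fell in 10 of 21 and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0426, and adjusted p = 0.353 with an estimated correlation), lost without 15 min replicate 2, adjusted p = 0.0745. Methionine synthase MET6 fell by 1.76. Chaperones rose in 15 of 26 and fell in 3 (16 and 6 adjusted over the list alone, camera adjusted p = 0.00152, and adjusted p = 0.236 with an estimated correlation), SSA4 by 4.58 ± 0.24. The mitochondrial ribosome rose in 26 of 67 (22 adjusted over the list alone, camera adjusted p = 2.84e-05, and adjusted p = 0.245 with an estimated correlation). Glucose signalling rose in 12 of 23 and fell in 2 (13 and 2 adjusted over the list alone, camera adjusted p = 0.00524, and adjusted p = 0.230 with an estimated correlation). TPK2 rose by 2.80 ± 0.23 and TPK3 fell by 2.72. Glycolysis had 5 of 21 higher and 4 lower (median -0.48 with a mean of 0.69 and a test direction of higher, camera adjusted p = 0.694).

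Most listed members of the galactose regulon were higher at 15 min, but not GAL10, GAL2, GAL80 or GAL1. Of 10 measured members 7 rose, also adjusted over the list alone (camera adjusted p = 0.000583, and adjusted p = 0.230 with an estimated correlation), PGM2 by 6.09 ± 0.25. GAL7 rose from 1.93 ± 1.14 to 8.23 ± 0.471 CPM, GAL3, the galactose sensor, from 6.68 ± 1.70 to 18.2 ± 1.17 CPM, and GAL4, the activator, from 4.42 ± 0.917 to 27.5 ± 3.79 CPM. MET17, which the strain lacks, had 28 and 32 reads in glucose and 25 and 26 at 15 min, all under 30 bp. Values of a few CPM, here and for GAL genes at other times, can thus hold misplaced short reads. GAL10 (0.66 ± 0.45), GAL2 (0.97 ± 0.51) and GAL80 (0.05 ± 0.18) did not pass. Neither did GAL1 (0.18 ± 0.32, adjusted p = 0.67), which was counted apart with the antisense RNA entries left out. PCL10 (0.73 ± 0.24) lost its call without either glucose library or either 15 min library, adjusted p = 0.0629 to 0.127, and with reads of at least 30 bp at 0.0986. Among hexose transporters 6 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00217, and adjusted p = 0.230 with an estimated correlation). HXT7 reached 811 ± 156 CPM, HXT2 1483 ± 177 CPM, HXT4 612 ± 57.9 CPM and HXT5 80.7 ± 46.1 CPM. HXT6 rose by 5.69 ± 0.31 and the sensor SNF3 by 1.94 ± 0.25. HXT1 fell by 0.78, a call lost without either glucose library or 15 min replicate 2, adjusted p = 0.0763 to 0.137, and with library totals at 0.107, while HXT3 (0.61 ± 0.28) did not pass.

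In all, 1408 genes were higher and 1512 lower at 15 min than in glucose, and 2856 did not pass. These were 1491 and 1556 with reads of at least 30 bp. Without scaling factors the median of all genes shifted by 0.32. Then 1952 genes were higher and 1053 lower, where the main scaling gave 48.2% of the calls as higher. The split between rises and falls at 15 and 60 min is thus relative to the scaling, while the 10 largest changes each way are far greater than that shift.

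**Figure D1:**
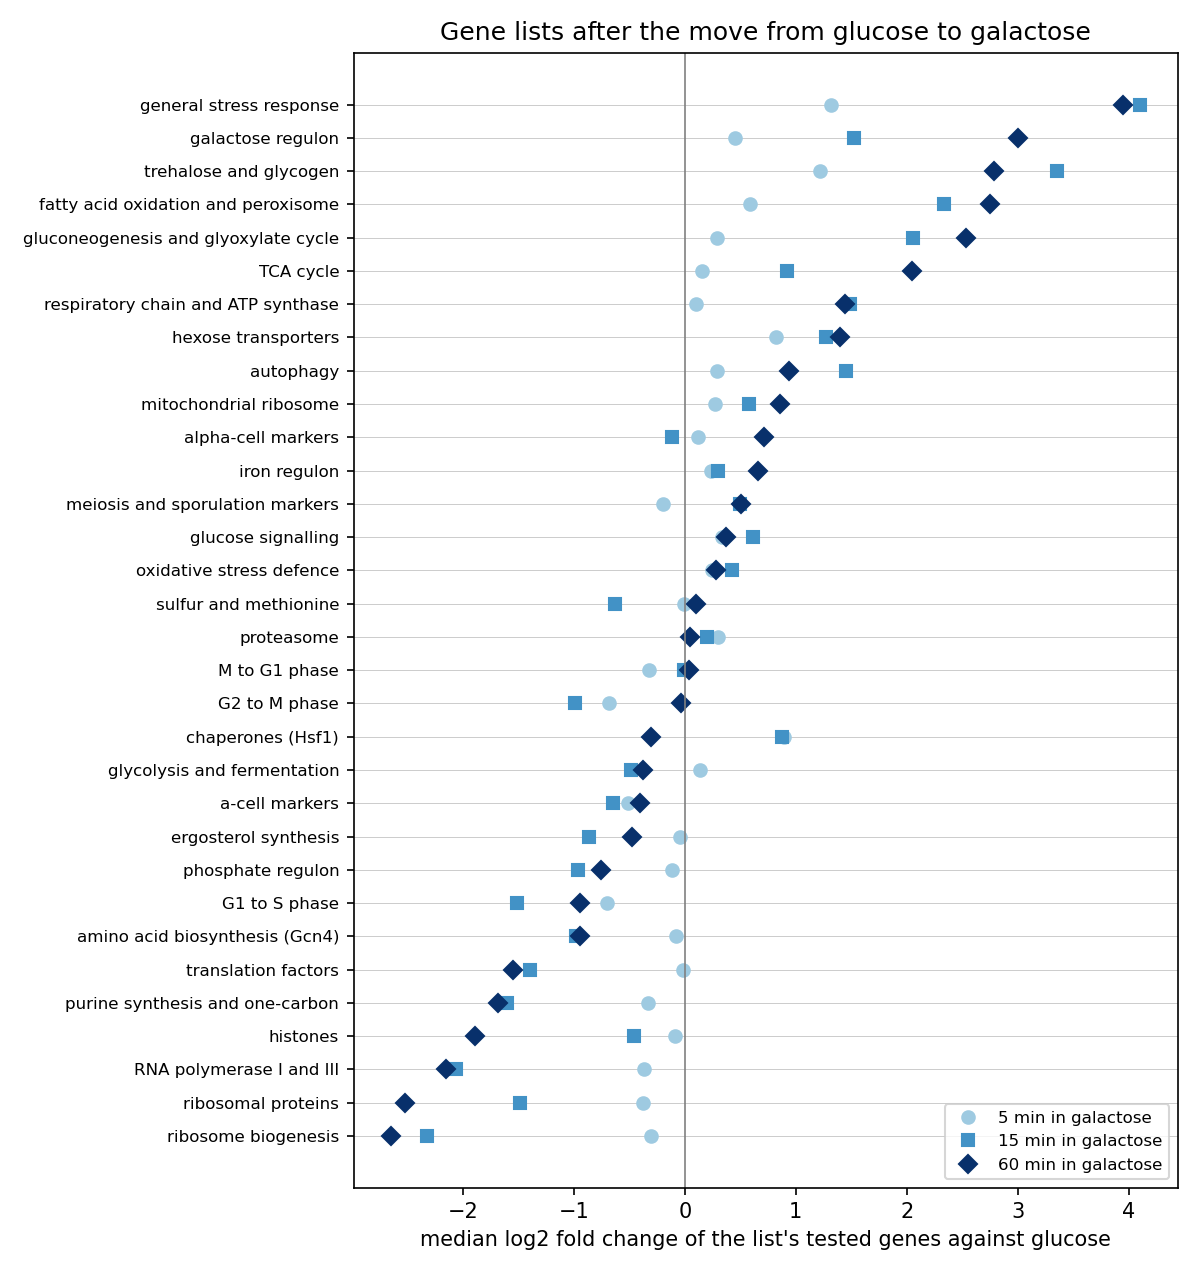
Median log2 fold change against glucose (horizontal axis) of 32 gene lists (vertical axis, sorted by the 60 min value), with 1 marker for each of 5, 15 and 60 min in galactose. At 60 min the medians run from -2.65 for ribosome biogenesis to 3.95 for the general stress response, while medians near 0 (translation factors, amino acid synthesis, sulfur, ergosterol and histones at 5 min, M to G1 phase and alpha-cell markers at 15 min, chaperones, G2 to M and M to G1 phase at 60 min) change sign between scalings.

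After 60 min the galactose genes had risen and transcripts of most ribosomal protein genes were lower still. GAL7, of galactose breakdown (YBR018C, chromosome II, 274427 to 275527, minus strand), went from 1.93 ± 1.14 to 25.1 ± 5.25 CPM. GAL10 (YBR019C, chromosome II, 276253 to 278352, minus strand) went from 2.81 ± 0.390 to 28.2 ± 2.70 CPM and the galactose permease GAL2 (YLR081W, chromosome XII, 290212 to 291936, plus strand) from 3.82 ± 3.81 to 32.7 ± 1.90 CPM. HXT1 (YHR094C, chromosome VIII, 290913 to 292625, minus strand) fell from 128 ± 1.10 to 4.93 ± 0.180 CPM and HXT3 from 276 ± 8.68 to 11.8 ± 5.52 CPM, while HXT7 rose from 11.9 ± 2.09 to 987 ± 133 CPM. JEN1, the carrier of lactate and pyruvate, went from 2.70 ± 1.03 to 1222 ± 272 CPM, and YEF3 fell from 15164 ± 827 to 1142 ± 43.1 CPM. Mitochondrial ribosomal RNA took 17.1% ± 0.515 of the reads (SD, n = 2), against 6.83% ± 0.322 in glucose, a measured feature of these libraries that stands beside each group below. The 10 most abundant genes took 27.1% and 28.7% of assigned reads in the 60 min libraries, against 20.6% and 19.5% in glucose.

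All 10 measured genes of the galactose regulon rose at 60 min, also adjusted over the list alone (median 3.01, camera adjusted p = 3.17e-06, and adjusted p = 0.203 with an estimated correlation). GAL7 rose by 3.19 ± 0.38, GAL2 by 3.07 ± 0.51, GAL10 by 2.94 ± 0.45 and GAL3 by 2.88 ± 0.25. MTH1 rose by 3.22 ± 0.31, GAL4 by 2.55 ± 0.38, GCY1 by 4.32 ± 0.27 and PGM2 by 5.38 ± 0.25, and PCL10 went from 25.5 ± 2.15 to 64.8 ± 10.8 CPM. The GAL10 call was lost when reads of both strands were counted (adjusted p = 0.153). GAL80, the repressor of GAL4, rose from 46.0 ± 2.58 to 71.7 ± 0.998 CPM, a call lost without glucose replicate 2 or either 60 min library, adjusted p = 0.0621 to 0.0833. GAL1, the galactokinase (YBR020W, chromosome II, 279021 to 280607, plus strand), could be counted only with the overlapping antisense RNA left out of the gene table. It was then at 8.03 ± 0.194 CPM in glucose, 4.34 ± 1.87 at 5 min, 9.31 ± 1.85 at 15 min and 32.5 ± 5.89 CPM at 60 min (log2 fold change 1.88 ± 0.32, adjusted p = 0.00104).

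Of the hexose transporter list 7 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0489, and adjusted p = 0.321 with an estimated correlation). The list call was lost without glucose replicate 1, either 5 min library or 60 min replicate 2, adjusted p = 0.0520 to 0.0889, and with library totals at 0.123. HXT7 (6.26 ± 0.26), HXT5, of slow growth (5.71 ± 0.38), HXT6 (4.44 ± 0.31), SNF3 (2.06 ± 0.25), HXT2 (1.62 ± 0.20) and HXT4 (1.46 ± 0.22) rose. So did HXT10 (1.34 ± 0.48), whose call was lost without glucose replicate 1, either 15 min library or either 60 min library, adjusted p = 0.0557 to 0.232. RGT2, the sensor of high glucose, was at 33.1 ± 1.37 CPM against 31.6 ± 1.52 CPM and did not pass.

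**Figure D2:**
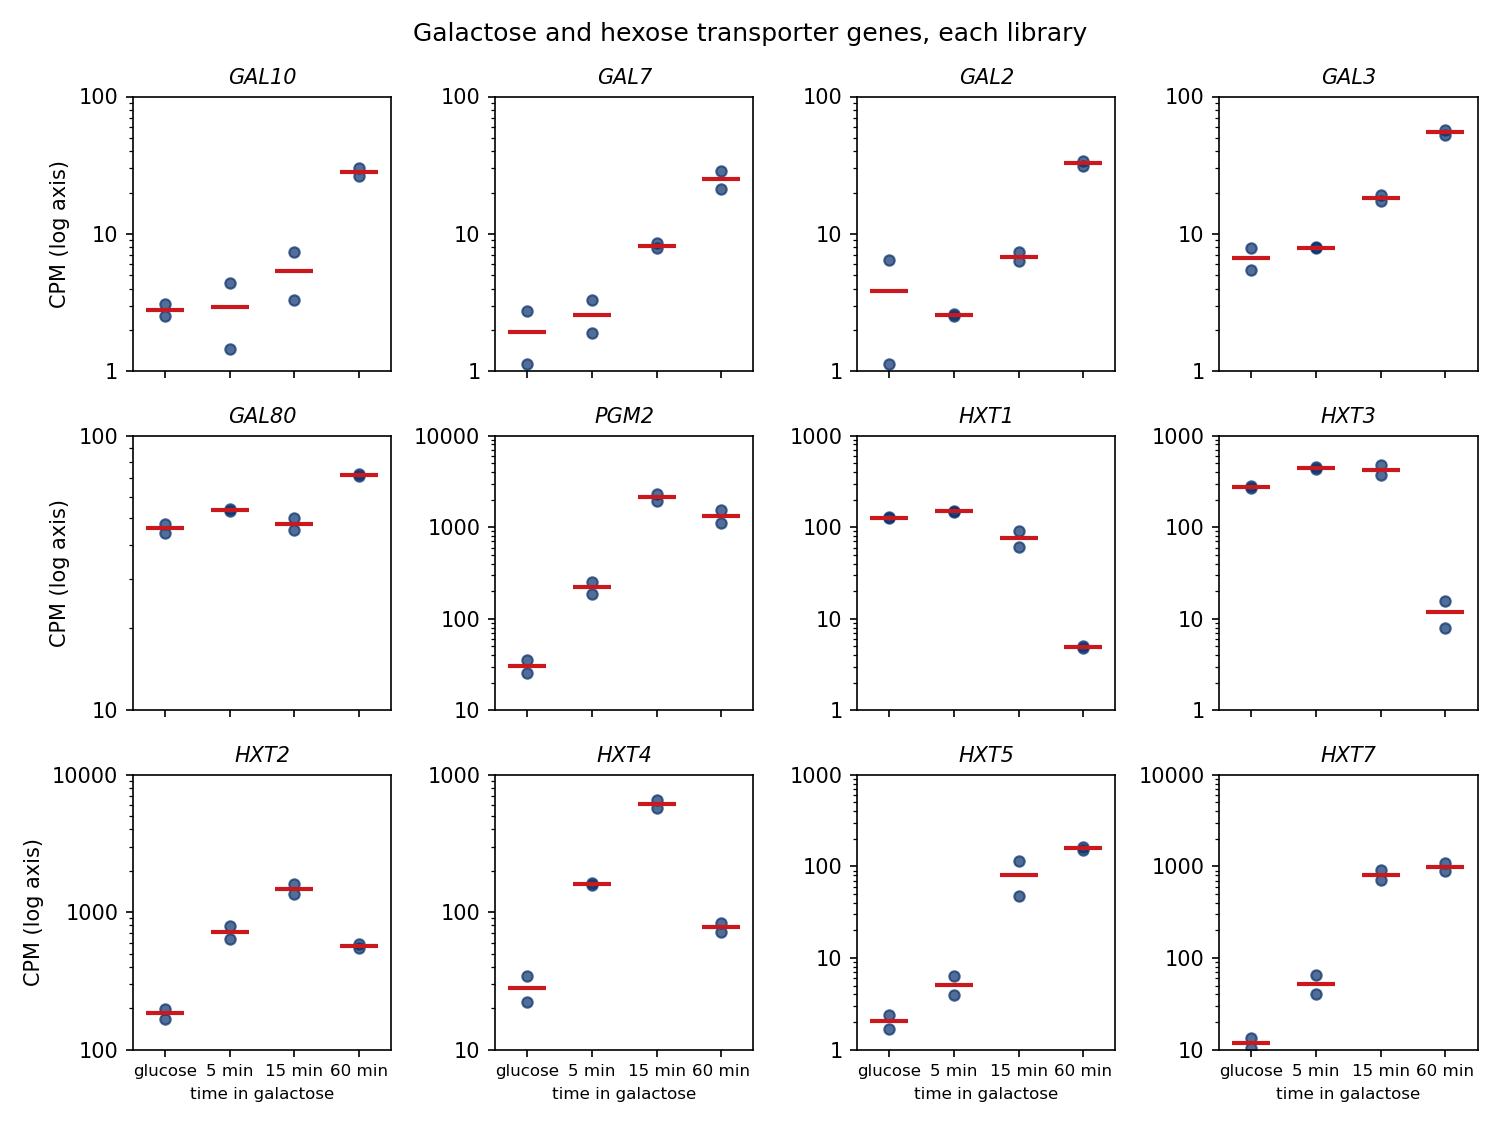
CPM of each library (dots) and the group mean (red bar) on a log axis, for 12 galactose and hexose transporter genes, against the group (glucose, and 5, 15 and 60 min in galactose). PGM2 rose from a mean of 30.6 to 2129 CPM by 15 min, GAL10, GAL7 and GAL2 stood at 28.2, 25.1 and 32.7 CPM at 60 min, and HXT1 and HXT3 were down to 4.93 and 11.8 CPM at 60 min while HXT7 reached 987 CPM.

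The largest rises at 60 min were RGI2 (log2 fold change 9.11 ± 0.44), HSP12 (8.80 ± 0.38), JEN1 (8.38 ± 0.40), TMA10 (8.05 ± 0.27), HXK1 (7.08 ± 0.30), and DDR2 (7.01 ± 0.41). They were followed by SPG4 (6.62 ± 0.47), the lactate dehydrogenase CYB2 (6.29 ± 0.40), HXT7 and the transaldolase NQM1 (6.25 ± 0.37). Among the largest falls were AAH1, adenine deaminase (-5.68 ± 0.34), the CTP synthase URA7 (-4.68 ± 0.38) and the GMP synthase GUA1 (-4.47 ± 0.22). The other falls of the rule were the helicase DBP2 (-4.91 ± 0.33), the hexose carriers HXT3 (-4.51 ± 0.28) and HXT1 (-4.44 ± 0.22), NSR1 (-4.45 ± 0.33), the karyopherin KAP123 (-4.42 ± 0.28), the acid phosphatase PHO3 (-4.38 ± 0.25) and SYO1, which escorts ribosomal proteins into the nucleus (-4.24 ± 0.32). Adjusted p for these genes ranged from 4.33e-07 (TMA10) to 1.26e-05 (URA7). Both libraries at 60 min lay on the same side of both in glucose, as the rule required.

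Ribosomal protein genes were lower in 137 of 138, also adjusted over the list alone (median -2.52, camera adjusted p = 1.31e-37, and adjusted p = 0.203 with an estimated correlation). RPL9A, which shares reads with its copy, went from 2982 ± 352 to 160.4 ± 19.6 CPM. Ribosome biogenesis genes were lower in 138 of 138, also adjusted over the list alone (median -2.65, camera adjusted p = 2.08e-36, and adjusted p = 0.203 with an estimated correlation). NOP7 was at -4.00 ± 0.23. The polymerase I and III subunits fell in 21 of 21, also adjusted over the list alone (camera adjusted p = 9.49e-10, and adjusted p = 0.203 with an estimated correlation), RPA135 by 3.74. Translation factors fell in 30 of 34 with 1 higher (31 lower adjusted over the list alone, camera adjusted p = 1.65e-09, and adjusted p = 0.216 with an estimated correlation). Histone genes, whose copies share reads, fell in 8 of 10, also adjusted over the list alone (median -1.89, camera adjusted p = 0.000713, and adjusted p = 0.326 with an estimated correlation). HTA2 went from 441 ± 40.5 to 46.0 ± 5.76 CPM. Purine synthesis fell in 13 of 17 (14 adjusted over the list alone, camera adjusted p = 4.20e-05, and adjusted p = 0.361 with an estimated correlation), IMD4 by 3.61. Amino acid synthesis fell in 26 of 39 with 1 higher, also adjusted over the list alone (camera adjusted p = 9.59e-06, and adjusted p = 0.361 with an estimated correlation). HIS1 was at -3.12 ± 0.28.

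Most genes of oxidative metabolism were higher at 60 min. The TCA cycle rose in 16 of 16, also adjusted over the list alone (median 2.05, camera adjusted p = 5.10e-09, and adjusted p = 0.203 with an estimated correlation), and CIT1 was at 1186 ± 225 CPM against 97.6 ± 5.01 CPM. The respiratory chain rose in 31 of 33, also adjusted over the list alone (camera adjusted p = 6.63e-11, and adjusted p = 0.216 with an estimated correlation). QCR2 was at 2.33 ± 0.20. The mitochondrial ribosome rose in 42 of 67 (46 adjusted over the list alone, median 0.86, camera adjusted p = 1.06e-09, and adjusted p = 0.203 with an estimated correlation). Fatty acid oxidation rose in 18 of 20 (18 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.03e-10, and adjusted p = 0.203 with an estimated correlation). POT1 was at 5.86 ± 0.34 and the carnitine acetyltransferase CAT2 at 4.93 ± 0.31. Gluconeogenesis rose in 15 of 18 (16 adjusted over the list alone, camera adjusted p = 1.86e-08, and adjusted p = 0.203 with an estimated correlation). Acetyl-CoA synthetase ACS1 was at 5.45 ± 0.32, the alcohol dehydrogenase ADH2 at 5.01 ± 0.40 and SUC2 at 4.85 ± 0.16. General stress genes stayed up in 44 of 46 (45 adjusted over the list alone, camera adjusted p = 6.48e-22, and adjusted p = 0.203 with an estimated correlation). Trehalose and glycogen genes were higher in all 18, also adjusted over the list alone (camera adjusted p = 1.07e-11, and adjusted p = 0.203 with an estimated correlation). Chaperones were split, 6 higher and 8 lower (median -0.30, which reaches 0.00 with library totals, camera adjusted p = 0.664). HSP42 was at 2.88 ± 0.32 and the Hsp40 protein YDJ1 at -2.38 ± 0.19.

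Other lists at 60 min went both ways. Autophagy rose in 18 of 28 and fell in 2 (19 and 2 adjusted over the list alone, camera adjusted p = 1.18e-05, and adjusted p = 0.215 with an estimated correlation), ATG8 by 2.79 ± 0.31. Ergosterol synthesis fell in 11 of 23, also adjusted over the list alone (camera adjusted p = 0.00903, and adjusted p = 0.432 with an estimated correlation), ERG3 by 1.78. Genes of G1 to S phase fell in 9 of 17 (10 adjusted over the list alone, camera adjusted p = 0.0170, and adjusted p = 0.203 with an estimated correlation), RNR1 by 1.78. Iron genes had 8 of 19 higher and 2 lower (camera adjusted p = 0.0954), with the cell wall mannoproteins FIT2 and FIT3 up by 5.18 ± 0.61 and 4.28 ± 0.38. Oxidative stress genes had 7 of 20 higher and 5 lower (camera adjusted p = 0.339), with the peroxiredoxin PRX1 at 3.40 ± 0.24 and the NADPH oxidoreductase OYE2 at -2.40 ± 0.27. Meiosis markers (camera adjusted p = 0.391), alpha-cell markers (0.565), M to G1 phase (0.623) and the strain deletions (0.769) did not pass at any time. Glycolysis had 5 of 21 higher and 7 lower (median -0.38 with a mean of 0.64 and a test direction of higher, camera adjusted p = 0.930).

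Altogether 1369 genes were higher and 1434 lower at 60 min than in glucose, and 2973 did not pass. With reads of at least 30 bp the counts were 1443 and 1485, and without the 15 min libraries 1273 and 1369. With library totals the median of all genes shifted by 0.30 and the counts were 1918 and 1048, so that higher calls went from 48.8% to 64.7%.

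Ribosome genes were lower and genes for stored and alternative carbon higher at 15 than at 5 min, with the limit on culture or strain stock given above. JEN1 went from 3.79 ± 2.25 to 341 ± 151 CPM, HSP12 from 33.5 ± 7.26 to 2516 ± 1503 CPM and POT1 from 1.59 ± 0.910 to 85.4 ± 27.4 CPM. RGI2 and FMP45 rose by 5.93 ± 0.44 and 4.71 ± 0.43. CGR1 fell from 59.6 ± 8.66 to 2.89 ± 1.39 CPM and SPB1 from 212 ± 17.4 to 13.7 ± 2.85 CPM. DBP7 (-3.68 ± 0.19) and RRP12 (-3.63 ± 0.25) were the other largest falls, beside a lower value of HIS3 (-5.30 ± 0.32) that is not read as a change over time. Ribosome biogenesis genes fell in 134 of 138 (135 adjusted over the list alone, camera adjusted p = 9.58e-37, and adjusted p = 0.204 with an estimated correlation). Ribosomal protein genes fell in 103 of 138 (110 adjusted over the list alone, camera adjusted p = 1.26e-19, and adjusted p = 0.303 with an estimated correlation). The respiratory chain rose in 30 of 33 (33 adjusted over the list alone, camera adjusted p = 1.70e-13, and adjusted p = 0.204 with an estimated correlation), QCR9 by 2.32 ± 0.24. Fatty acid oxidation rose in 17 of 20 with 1 lower, also adjusted over the list alone (camera adjusted p = 3.36e-09, and adjusted p = 0.204 with an estimated correlation). FOX2 was at 2.44 ± 0.19. General stress genes rose in 43 of 46 (45 adjusted over the list alone, camera adjusted p = 1.57e-22, and adjusted p = 0.204 with an estimated correlation).

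Members of the galactose regulon rose in 6 of 10 between 5 and 15 min, also adjusted over the list alone (camera adjusted p = 0.00141, and adjusted p = 0.204 with an estimated correlation). PGM2 rose by 3.27 ± 0.25, GCY1 by 2.31 ± 0.27 and MTH1 by 1.59 ± 0.31. The rises of GAL3 (1.10 ± 0.25) and GAL4 (1.49 ± 0.38) were lost without 15 min replicate 2, adjusted p = 0.0610 and 0.0896. GAL7 (1.39 ± 0.38) was lost without 5 min replicate 2 or either 15 min library, adjusted p = 0.0642 to 0.0845. Hexose transporters rose in 6 and fell in 1, also adjusted over the list alone (camera adjusted p = 0.00225, and adjusted p = 0.204 with an estimated correlation). HXT7 (3.96 ± 0.26), HXT5 (3.64 ± 0.38) and HXT4 (1.93 ± 0.22) were among the rises, as was HXT6, which shares reads with HXT7. HXT1 fell from 149 ± 2.30 to 75.4 ± 20.7 CPM, lost without 15 min replicate 2, adjusted p = 0.0631. Together 939 genes were higher and 1274 lower at 15 min than at 5 min, and 3563 did not pass. The counts were 447 and 743 without 15 min replicate 2, and 965 and 1289 with reads of at least 30 bp. With library totals (median shift 0.23) they were 1386 and 936, so that higher calls went from 42.4% to 59.7%.

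From 15 to 60 min most chaperone and histone genes fell, and most genes of G2 to M phase rose. HSP30 fell from 456 ± 113 to 8.08 ± 4.65 CPM, BTN2 from 484 ± 8.36 to 11.9 ± 3.22 CPM and HXT3 from 426 ± 73.3 to 11.8 ± 5.52 CPM. MGA1 (-4.30 ± 0.41) and HXT1 (-3.66 ± 0.22) were the other largest falls. ADH2, which oxidises ethanol, rose from 29.1 ± 17.0 to 949 ± 335 CPM, PCL1 from 7.26 ± 0.896 to 93.4 ± 5.54 CPM and ACS1 from 55.0 ± 14.6 to 523 ± 162 CPM. PDH1 (3.75 ± 0.32) had the other largest rise, beside a higher value of HIS3 (4.32 ± 0.32) that is not read as a change over time. Chaperones fell in 18 of 26 and rose in 0 (20 lower adjusted over the list alone, camera adjusted p = 1.08e-10, and adjusted p = 0.271 with an estimated correlation). SSA4 was at -3.49 ± 0.24. Genes of G2 to M phase rose in 7 of 12 (8 adjusted over the list alone, camera adjusted p = 5.25e-06, and adjusted p = 0.295 with an estimated correlation), the cyclin CLB2 by 2.08 ± 0.21. Genes of G1 to S phase rose in 4 of 17 (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000837, and adjusted p = 0.271 with an estimated correlation), CLN1 by 2.67 ± 0.34.

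Ribosomal protein genes fell further from 15 to 60 min, 86 of 138 lower and 2 higher (109 and 3 adjusted over the list alone, median -1.08, camera adjusted p = 1.41e-26, and adjusted p = 0.417 with an estimated correlation). Ribosome biogenesis genes went both ways, 29 lower and 9 higher (median -0.18, camera adjusted p = 0.0768). Histone genes fell in 7 of 10 (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 3.41e-05, and adjusted p = 0.417 with an estimated correlation). HTA2 was at -2.75 ± 0.21. Trehalose and glycogen genes fell in 7 of 18 and rose in 2, also adjusted over the list alone (camera adjusted p = 0.0112, and adjusted p = 0.616 with an estimated correlation), lost without 15 min replicate 2 or 60 min replicate 1, adjusted p = 0.0545 to 0.171, and with fry at 0.0574. The TCA cycle rose in 8 of 16 (10 adjusted over the list alone, camera adjusted p = 1.43e-06, and adjusted p = 0.413 with an estimated correlation). LSC2 was at 2.24 ± 0.23. Galactose genes rose in 4 of 10 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00554, and adjusted p = 0.295 with an estimated correlation). GAL3 rose by 1.54 ± 0.25. GAL10 (2.28 ± 0.45) was lost without 15 min replicate 1 or either 60 min library, adjusted p = 0.0621 to 0.0957. GAL2 (2.10 ± 0.51) was lost without either 15 min library or either 60 min library, adjusted p = 0.0773 to 0.147, and GAL7 (1.49 ± 0.38) without either 15 min library or either 60 min library, adjusted p = 0.106 to 0.158. HXT2 and HXT4 fell by 1.39 and 2.96 from their levels at 15 min, and HXT6 by 1.25 (lost without either 15 min library or 60 min replicate 2, adjusted p = 0.113 to 0.203).

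The comparison of 60 with 15 min called 442 genes higher and 497 lower, and 4837 did not pass. The higher genes numbered 692 without 5 min replicate 1, 188 and 206 without 15 min replicates 1 and 2, and 139 and 81 without 60 min replicates 1 and 2. The lower genes numbered 195 without 15 min replicate 1, and 234 and 136 without 60 min replicates 1 and 2. Both counts rose with reads of at least 30 bp, to 492 and 535. Of the 109 named calls of this comparison, 58 were lost without at least 1 library.

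Genes that rose early mostly stood in the later lists too. Of the 322 genes higher at 5 min, 300 were also higher at 15 min and 257 at 60 min, where independent lists would share 78.5 and 76.3. Of the 29 lower genes 28 and 20 were also lower, where 7.59 and 7.20 would be shared. Between 15 and 60 min 1050 higher and 1103 lower genes were shared, against 334 and 375 for independent lists, and 12 went opposite ways (7 between 5 and 60 min and 0 between 5 and 15 min). All 3 contrasts use the same glucose libraries. In 20 simulations without any effect 0 genes were called in both. Without an effect hardly any gene can be called in either contrast, so this does not measure the overlap that shared libraries give among called genes. The simulated fold changes still correlated with r = 0.512 (5 and 15 min), 0.498 (15 and 60 min) and 0.506 (5 and 60 min), against observed values of 0.700, 0.866 and 0.540. Covariances were 0.586, 1.62 and 0.466, beside simulated ones of 0.0580, 0.0576 and 0.0582. Part of the excess may come from the shared controls, since the glucose libraries were not split, which would leave 1 per comparison.

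Reads on the strand opposite to genes made up a larger share at 15 and 60 min than in glucose, and not at 5 min. Among reads of at least 30 bp, a limit chosen after seeing the data, the antisense share of reads in genes was 0.640% ± 0.00237 in glucose, 0.584% ± 0.136 at 5 min, 0.998% ± 0.00604 at 15 min and 1.13% ± 0.0747 at 60 min (SD, n = 2). With all reads the shares were 1.80% ± 0.565, 1.46% ± 0.881, 3.01% ± 0.282 and 2.58% ± 0.412. Replicate 2 then had the higher share in every group, as with 1.41% and 2.20% in glucose and 2.81% and 3.21% at 15 min. It also held more reads under 30 bp in every group. These SDs thus include a difference by replicate number, which the main antisense test left out. Among reads of at least 30 bp replicate 2 was higher at 5 and 60 min alone. With 2 libraries against 2 an exact permutation test cannot go below 0.333, so the shares are given as values. Over HOS4, a subunit of the Set3 complex (YIL112W, chromosome IX, 151595 to 154846, plus strand), antisense reads of at least 30 bp went from 1.28 ± 0.218 to 47.9 ± 7.72 CPM at 15 min (log2 fold change 4.42 ± 0.35, adjusted p = 1.77e-10). Over MIG2, a gene of glucose repression, they went from 0.762 ± 0.546 to 15.5 ± 0.791 CPM at 60 min. In the other direction, antisense reads over CAT8, an activator of gluconeogenesis, fell from 17.7 ± 1.72 to 3.49 ± 0.831 CPM at 15 min, and over GAC1, a glycogen phosphatase subunit, from 11.9 ± 1.78 to 0.614 ± 0.221 CPM at 60 min.

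With reads of at least 30 bp, 604 genes could be tested for antisense reads by limma, and 33 were higher and 15 lower at 5 min, 192 and 87 at 15 min, and 148 and 94 at 60 min than in glucose. The other largest rises were LDS2 (3.71 ± 0.33), FZF1 (3.62 ± 0.36), HIS1 (3.61 ± 0.41) and YFL051C (3.60 ± 0.37) at 15 min, and YFL051C (3.72 ± 0.37), NUD1 (3.62 ± 0.35), HIS1 (3.45 ± 0.41) and GTO3 (2.91 ± 0.40) at 60 min. With all reads 2175 genes were tested, and the calls were 0 higher and 0 lower at 5 min (91 genes at an unadjusted p under 0.05), 78 and 10 at 15 min, and 2 and 0 at 60 min. The median antisense log2 fold change per gene was 0.28 at 15 min and -0.05 at 60 min with all reads. It was 0.32 and 0.22 with reads of at least 30 bp.  The largest rises with all reads at 15 min, over YEL009C-A, YKU70, THR1, MIX17 and KTR2 (4.46 to 6.26), rest on the short reads placed in that group alone. Single libraries moved the counts with all reads, except the higher one at 5 min. The higher genes at 15 min numbered 26 and 46 without glucose replicates 1 and 2, 144 and 132 without 5 min replicates 1 and 2, and 5 and 0 without 15 min replicates 1 and 2. The lower genes at 15 min numbered 1 and 6 without the glucose libraries, 14 and 18 without the 5 min libraries, 0 without either 15 min library and 6 without either 60 min library. At 60 min 26 and 22 genes were higher and 8 and 9 lower without 5 min replicates 1 and 2, and 0 were called without any other single library. At 5 min 27 were lower without 5 min replicate 2.

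**Figure D3:**
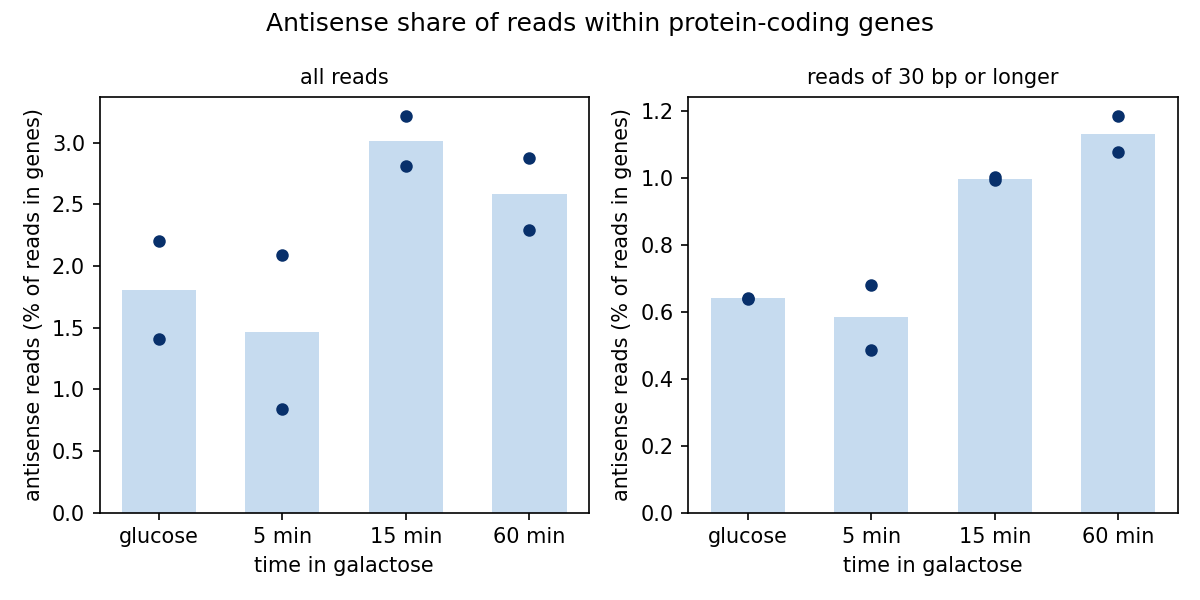
Antisense share of the reads in protein-coding genes, in percent, per library (dots) with the group mean (bars), for all reads and for reads of at least 30 bp, against the group. With reads of at least 30 bp the 4 libraries at 15 and 60 min lie between 0.994% and 1.18%, above both glucose libraries (0.638% and 0.641%).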

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

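Of the tests in this part, those of read totals and of a batch or culture of their own for the 15 min libraries, of short reads for the antisense share, and of nuclear RNA and rRNA removal for the mitochondrial rRNA were chosen only after the results were seen, as was the use of reads of at least 30 bp.

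Some genes were higher than glucose at 15 min and lower at 60 min, or the reverse, with the difference between the times itself tested by limma. FES1, a nucleotide exchange factor of Hsp70 (YBR101C, chromosome II, 443821 to 444693, minus strand), was at 2.53 (log2 fold change against glucose) at 15 min and -0.54 at 60 min, a difference of -3.07 ± 0.17 (adjusted p = 2.54e-05). ATG5, of autophagosome formation, was at 1.27 and -0.56, a difference of -1.83 ± 0.21 (adjusted p = 0.000797). MET2, a homoserine acetyltransferase of methionine synthesis, went the other way, with -0.74 at 15 min and 1.65 at 60 min, a difference of 2.38 ± 0.26 (adjusted p = 0.000649). The negative values of these genes are small and relative to the scaling. With library totals the median of all genes shifted upward by 0.32 at 15 min and 0.30 at 60 min. The difference between the times does not itself test whether a gene lay below glucose.

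Reads shorter than 30 bp piled up at 186 places of 10 bp in both 15 min libraries (10003 and 15219 reads) and at 0 such places in each other group, a signal in short reads, which make up 3.54% to 8.81% of the libraries. Only 1.76% of the reads that start there reached 30 bp, against 93.4% at 210 places shared by all 8 libraries, which argues against RNA made from these loci. Of the places inside genes 51.6% lay on the sense strand, against 73.6% at shared places, which argues against sense transcripts of those genes. The 15 min libraries held on average 82.4% of the reads of the other 6, a mean raised by 5 min replicate 1 (8393099 reads). Glucose replicate 1 (4374466), 5 min replicate 2 (3753562) and 60 min replicate 1 (3863617) also held more reads than either 15 min library (3685285 and 3547179). They lacked these places, which argues against more reads as the cause. A library batch, culture or strain stock of their own for the 15 min libraries (186 places in this group alone, 23 short-read places missing in it alone, and 7 places of longer reads missing in it alone, all in HIS3) cannot be told apart from the time in galactose, and a biological difference at 15 min stays open as untested.

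The antisense share of reads in genes was higher in all 4 libraries at 15 and 60 min than in both glucose libraries. Among reads of at least 30 bp it was still 1.66 times that in glucose, which argues against short reads aligned by chance as the whole cause. Short reads carried much of the share with all reads, however. It was 1.80% in glucose and 3.01% at 15 min with all reads, against 0.640% and 0.998% with reads of at least 30 bp. Short reads may therefore account for much of the rise seen with all reads. In reads of at least 30 bp the antisense share was 1.69 times that in glucose when only parts over 600 bp from other annotated genes were searched. This argues against transcription running on within 600 bp of annotated neighbours as the whole cause. Longer run-on, or run-on from unannotated transcripts, was not tested. Leaving out the ribosome lists gave 1.39 times, and leaving out the 10 genes with most antisense reads 1.61 times, which argues against either alone as the whole cause, although fewer sense reads of ribosome genes may account for part of the rise. Both sets were not left out together. A biological rise of antisense transcription in galactose stays open as a hypothesis found and examined on the same 8 libraries.

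Mitochondrial rRNA took 17.1% ± 0.515 of reads at 60 min and 6.83% ± 0.322 in glucose. By limma neither the 15S (adjusted p = 0.162) nor the 21S rRNA (adjusted p = 0.0682) passed at 60 min. The share of mitochondrial rRNA in reads of at least 30 bp was 2.55 times that in glucose, which argues against short reads aligned by chance. Less nuclear RNA at 60 min stays open, since rRNA minus mRNA of the mitochondrion changed by 0.58 log2, with 7.10 and 7.43 in the 60 min libraries, 6.50 and 6.86 in glucose, and 7.08 in a 5 min library. Less complete removal of rRNA also stays open, since nuclear rRNA changed 0.434 times but its reads are mostly absent from the deposited lists (0.0211% to 0.0797% of assigned reads). A biological change of mitochondrial rRNA in galactose was not tested.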

How the results depend on the processing

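The settings chosen only after the results were seen were reads of at least 30 bp, the fit without the 15 min libraries and the gene table without antisense RNA. Of 652 gene results named by the rule, 554 were called and 0 reversed in any setting. With library totals 631 were the same, 18 weaker and 3 stronger. The same held for 616 of 628 with reads of at least 30 bp, 229 of 246 without the 15 min libraries and 630 of 652 with the replicate block.

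Where a count moved by more than 1.5 times the cause was not tested, except that stricter thresholds and fits of only the 4 libraries compared call fewer genes by construction. At 5 min the 322 higher genes were 172 at adjusted p below 0.01 and 133 with only 4 libraries. The 29 lower genes were 17 with library totals, 47 with voom, 18 at an absolute log2 fold change of at least 1, 4 at adjusted p below 0.01, 46 with position duplicates collapsed, 19 without the 15 min libraries and 10 with only 4 libraries. At a log2 fold change of at least 1 the 1512 lower genes at 15 min were 1003, the 939 higher and 1274 lower from 5 to 15 min were 618 and 788, and the 442 higher from 15 to 60 min were 212. At adjusted p below 0.01 the counts from 5 to 15 min were 527 and 825, and from 15 to 60 min 133 and 193. Apart from the fits that leave out 1 library, all other counts of genes stayed within 1.5 times.

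Gene lists called by camera at the preset correlation numbered 11 higher and 7 lower at 5 min, 12 and 11 at 15 min, 10 and 9 at 60 min, 10 and 9 from 5 to 15 min, and 9 and 4 from 15 to 60 min. With an estimated correlation all of these counts were 0, with a smallest adjusted p of 0.215, 0.230, 0.203, 0.204 and 0.271 in that order. The list calls thus rest on the preset value. The estimated version rests on 4 residual degrees of freedom and has little power. Even ribosome biogenesis at 60 min, with every tested member called lower, did not pass with it. Its loss of calls therefore does not show that the lists did not move. With fry 3 lists were lower at 5 min. Fry, which tests each list on its own, called 10 higher at 5 min, 14 and 13 at 15 min, and 14 and 11 at 60 min.

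Antisense counts depended on the setting throughout. At 5 min (0 higher and 0 lower) they were 2 higher with factors from antisense reads, 2 with the replicate block, 6 higher and 1 lower with duplicates collapsed, and 33 and 15 with reads of at least 30 bp. At 15 min (78 and 10) they were 183 higher and 27 lower with the block, 192 and 87 with reads of at least 30 bp, 18 lower with antisense factors and 16 lower with duplicates collapsed. At 60 min (2 and 0) 0 were higher at a distance of 600 bp, 12 higher and 5 lower with antisense factors, 38 and 20 with the block, 69 and 31 with duplicates collapsed, and 148 and 94 with reads of at least 30 bp. From 5 to 15 min (89 and 7) 264 were higher and 11 lower with the block, 16 lower with antisense factors, 3 lower with duplicates collapsed and 22 lower with reads of at least 30 bp. From 15 to 60 min (4 and 59) 15 were higher and 132 lower with the block, 18 lower with duplicates collapsed, and 30 higher with reads of at least 30 bp.

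With each library left out in turn, the lone library left in its group is assumed to vary like the other groups. Higher and lower genes then ranged from 175 to 487 and 4 to 453 at 5 min, 961 to 1665 and 1054 to 1696 at 15 min, 987 to 1656 and 1012 to 1612 at 60 min, 447 to 1178 and 743 to 1286 from 5 to 15 min, and 81 to 692 and 136 to 718 from 15 to 60 min. Genes changed at any time ranged from 2600 to 4006. Lists ranged from 10 to 11 and 5 to 8, 12 to 12 and 9 to 12, 9 to 10 and 9 to 10, 10 to 11 and 8 to 10, and 9 to 10 and 3 to 6 in the same order. Antisense counts ranged from 0 to 0 and 0 to 27, 0 to 144 and 0 to 18, 0 to 26 and 0 to 9, 0 to 528 and 0 to 10, and 0 to 8 and 0 to 73. The fits that leave out a library were not made for antisense reads of at least 30 bp. The count-model alternative was not run. With every library thinned to the smallest total, 282 genes were higher and 27 lower at 5 min, and the counts were 1352 and 1429 at 15 min, and 1302 and 1337 at 60 min. In simulated data 30% of changes of 2 times and 92% of 4 times were recovered, which was not split by depth.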

Other observations

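Of the tests below, those that use reads of at least 30 bp were chosen only after the results were seen.

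Some tRNA genes and small nucleolar RNAs were lower at 60 min. At that time 57 of 118 tRNA genes were lower than in glucose and 0 higher (median log2 fold change -1.21), where at 15 min 3 were lower and 1 higher (median -0.17). Small nucleolar RNAs, which guide rRNA modification, were lower in 19 of 68 at 60 min and higher in 0 (median -0.67), and at 15 min higher in 4 and lower in 0 (median 0.07). The RNA of the signal recognition particle fell by 1.19 at 60 min, while the RNAs of RNase P (-0.90) and RNase MRP (-0.76) did not pass. Reads of tRNA genes made up 0.255% and 0.577% of the glucose libraries and 0.239% and 0.200% of those at 60 min. From 15 to 60 min 18 tRNA genes and 8 small nucleolar RNAs were lower, with medians of -1.07 and -0.89. Reads of tRNA genes with identical copies can be shared or lost between copies.

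Messages of the mitochondrial genome rose in part. At 60 min 3 of 9 were higher than in glucose and 0 lower (median 0.56): ATP8 and OLI1, subunits of ATP synthase, by 1.07 ± 0.34 (adjusted p = 0.0275) and 0.67 ± 0.21 (adjusted p = 0.0286), and VAR1, a mitochondrial ribosomal protein, by 0.85 ± 0.28 (adjusted p = 0.0310). These genes were chosen after their values were seen. The mitochondrial rRNAs 15S and 21S had values of 0.73 (adjusted p = 0.162) and 1.17 (adjusted p = 0.0682).

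Antisense reads of at least 30 bp from 15 to 60 min fell over SNF11 (-3.23 ± 0.41), HOS4 (-2.55 ± 0.35) and JEN1 (-2.03 ± 0.37). Of the antisense reads of that length, 9.88% lay over HPF1, 9.43% over YLR162W and 4.42% over CSS1. HIS3, of which the strain keeps a part, had 1159 and 1552 reads in the glucose libraries, 4059 and 1054 at 5 min, 46 and 27 at 15 min, and 807 and 509 at 60 min.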
